A study of Mus musculus with 7 samples.

How the data were processed

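ChIP-seq was carried out on branchial arches dissected from mouse embryos at 10.5 days post coitum. Per the labels' protocols, cells from about 200 arches were cross-linked for 40 min with the protein cross-linker EGS at 1.5 mM, and 1% formaldehyde was present for the final 20 min. Chromatin was sheared for 8 min and precipitated with antibodies against β-catenin, against Pygo2 or with IgG, and libraries were made with an Illumina TruSeq ChIP kit. The 7 libraries are each a group of their own (input BA1 and BA2, IgG BA1, β-catenin BA1 and BA2, Pygo2 BA1 and BA2), since the labels do not say what separates BA1 from BA2. The peak lists of the β-catenin BA2 and Pygo2 BA2 libraries were used. Peak lists of the other libraries were not analysed here.

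The authors called the peaks with HOMER findPeaks in its factor style, per the file headers, with 1 library per list and no pooling. The headers name the IgG BA1 library as the control of both lists, whereas the deposited names of the lists mention IgG together with BA2; the headers were followed, and an IgG BA2 library was not analysed here. Each peak had to reach a false discovery rate of 0.001 on tag counts (at least 11 tags for β-catenin and 10 for Pygo2), at least 2-fold more tags than IgG and than the surrounding 10 kb, and a Poisson p-value of 1e-04 or less in each of these comparisons. At most 1 tag per position was counted. The fragment length was 168 bp for β-catenin and 166 bp for Pygo2, and the minimum distance between peaks 336 bp and 332 bp, per the file headers. The submitters' processing notes name Bowtie, Bowtie2, HOMER and the build mm10, without versions or roles. The deposited lists hold the coordinates of each peak, a name and a score; every peak has a width of 169 bp (β-catenin) or 167 bp (Pygo2). The deposited score is 1 for every peak, so it carries no peak strength, and the tag counts and fold changes per peak that the headers name were not used here.

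Because neither score nor width ranks the peaks, their position in the deposited list was used in its place, a choice made after the data were examined. The headers do not state the sort order. The numbers in the peak names rose along the list within each chromosome of at least 10 peaks (Spearman's rho from 0.756 to 0.971 for β-catenin and from 0.957 to 0.990 for Pygo2, over 20 chromosomes). Coordinates are given 1-based on mm10. Genes came from a RefSeq table of GRCm38.p6, the same assembly; the 21887 protein-coding genes with a chromosome were used, and all 469 symbols of the gene lists matched. The table gives no strand and no exons. Distances that had been planned to start sites were therefore measured from the peak centre to the nearer end of a gene, and exons, introns, UTRs and promoters were not told apart. The planned motif tests were not run, since no genome sequence was used here.

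The computations were done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. Peaks were called shared at an overlap of at least 1 bp. The expected overlap came from 10000 random placements of the β-catenin peaks on their chromosomes between the first and last peak of either list. Expected gene end shares came from 1000 placements of each list. For gene lists, the number of genes with a peak within 50 kb of an end was compared with 10000 random lists of protein-coding genes of the same size, matched in 10 classes on the distance between the flanking genes, which is a permutation of gene labels within classes, with Benjamini-Hochberg adjustment over 15 lists within each peak list and separately for high and low counts. These p-values describe the positions in 1 library per protein and not the spread between embryos. Genes close together can share a peak, which the matched lists do not copy, so 1 gene per 200 kb was kept as an alternative. List positions of shared and unshared peaks were compared by a two-sided permutation test with 100000 resamples. On simulated data, 200 planted overlaps among 1079 randomly placed peaks gave an excess of 203 and 50 planted overlaps an excess of 48.9. In a simulated test of gene lists over 21887 genes, 99% of 100 lists of 30 genes passed 0.05 when each gene gained a peak with a probability of 40%, and 1% of lists without added peaks. That effect is larger than the shares seen near β-catenin peaks, so the 99% is not the power for these.

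The gene lists, the main tests and the rule for naming genes were fixed before the data were examined. List position then took the place of the score, and gene ends that of start sites, in these tests and in this rule. The rule named the nearest protein-coding genes of the 15 first-listed peaks of each list and of the 10 shared positions with the lowest sum of list positions, and up to 10 members each of the Wnt target, heart development and arch patterning lists with a shared peak within 50 kb. Other list members that are named had a peak in the window and were picked as examples after their values were seen. Results for some single list members are not reported here. Alternatives were other overlap rules and placements, the first-listed part of each list, other windows and assignments of peaks to genes, and removal of peaks at gene ends. The lists have 1 library each, so no replicate could be left out.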

Results

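Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map β-catenin and Pygo2 on chromatin of the branchial arches of mouse embryos at 10.5 days post coitum. The branchial arches are the paired swellings below the embryonic head that form parts of the face, the neck and the vessels leaving the heart. β-catenin is the nuclear effector of canonical Wnt signalling, and Pygo2 is a PHD-finger protein that is bridged to it by Bcl9. The 7 libraries described here comprise input from BA1 and BA2, an IgG control from BA1, and ChIPs for β-catenin and for Pygo2 from BA1 and BA2. The labels do not state whether BA1 and BA2 name different arches or repeat collections. The analysed data are 2 peak lists, one for the β-catenin BA2 library and one for the Pygo2 BA2 library, each called against the IgG BA1 library, per the file headers. Each list therefore rests on 1 library, and no value below has a replicate error. Intervals on shares are 95% Wilson intervals and cover counting error only. The β-catenin library held 13672937 tags and the Pygo2 library 15009636 tags.

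The Pygo2 list was longer than the β-catenin list, and peaks of both proteins were concentrated at the ends of protein-coding genes. The Pygo2 list held 7150 peaks and the β-catenin list 1079 peaks, a ratio of 6.63. Within 1 kb of a gene end lay 3269 Pygo2 peaks (45.7%, interval 44.6 to 46.9%) and 373 β-catenin peaks (34.6%, interval 31.8 to 37.5%). Peaks inside genes but further from their ends made up 31.3% of the Pygo2 list and 33.6% of the β-catenin list, and intergenic peaks 23.0% and 31.8%. Random positions on the same chromosomes fell within 1 kb of a gene end at 3.29% for Pygo2 and 3.23% for β-catenin, so the observed shares were 13.9-fold and 10.7-fold higher (permutation of peak positions, one-sided p = 0.000999 for each, the smallest that 1000 placements can give). The gene end share was lower for β-catenin than for Pygo2 (odds ratio 0.627, interval 0.549 to 0.717, Fisher's exact test, two-sided p = 4.45e-12, which compares these 2 libraries). When the Pygo2 list was shortened to its 1079 first-listed peaks, its gene end share was 70.5% and the odds ratio 0.221. The gene table used gives no strand, so a gene end is the start or the end of a gene, and promoters could not be separated from 3′ ends.

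Peaks of both libraries rested on few tags. Tags in peaks were 15795 for β-catenin, 0.116% of the library (interval 0.114 to 0.117%), and 111009 for Pygo2, 0.740% (interval 0.735 to 0.744%). This gives a mean of 14.6 tags per β-catenin peak and 15.5 per Pygo2 peak, against calling minimums of 11 and 10 tags. Of 4036 putative β-catenin peaks, 2837 (70.3%) were removed by the comparison with IgG, and of 21859 putative Pygo2 peaks 12515 (57.3%) were removed.

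The question of whether β-catenin and Pygo2 sit at the same places was addressed by overlapping the lists. They shared 273 positions at an overlap of at least 1 bp, which is 25.3% of the β-catenin peaks (interval 22.8 to 28.0%). Random placement of the β-catenin peaks on their own chromosomes gave a mean of 1.15 shared peaks and at most 7 in 10000 placements, so the observed number was 237-fold higher (permutation of peak positions, one-sided p = 0.0001, the smallest these placements can give). Placements that kept each peak's distance class to the nearest gene end gave a mean of 6.17, and the fold was then 44.3. For the 373 β-catenin peaks at gene ends alone, 140 were shared, against a mean of 9.55 when they were placed at other gene ends of the same chromosome. Away from gene ends, 133 of 706 β-catenin peaks were shared, against a mean of 0.491 at positions of the same distance class. At the level of genes, 440 of 21887 protein-coding genes had a β-catenin peak within 1 kb of an end, and 295 of these (67.0%) also had a Pygo2 peak there, where independent lists would share 72.7 (odds ratio 11.1, across genes, which are not independent replicates). Because both lists were called against the same IgG library, part of this excess may come from the shared control, whose tag counts per peak were not used here. The placements and the gene comparison were also not matched on gene activity or open chromatin. A separate preference of each protein for active genes or open chromatin was therefore not told apart from binding together.

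Shared β-catenin peaks lay at gene ends more often than unshared ones. The share was 51.3% of 273 shared and 28.9% of 806 unshared β-catenin peaks (Fisher's exact test, two-sided, odds ratio 2.59, p = 4.09e-11). For Pygo2 the corresponding values were 51.3% and 45.5%, a difference that did not pass the threshold (Fisher's exact test, two-sided, odds ratio 1.26, p = 0.0632). Shared peaks were also listed earlier: their median position was at 30.5% of the β-catenin list against 55.0% for unshared peaks, and at 25.6% of the Pygo2 list against 51.2% (permutation test of the medians, two-sided, p = 1e-05 for each, the smallest that 100000 resamples can give). The gene end share of Pygo2 peaks was 70.8% in the first 10% of the list and 19.7% in the last 10%. For β-catenin it was 18.5% in the first 10%, 43.5% in the next 10% and 19.6% in the last 10%.

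**Figure D1:**
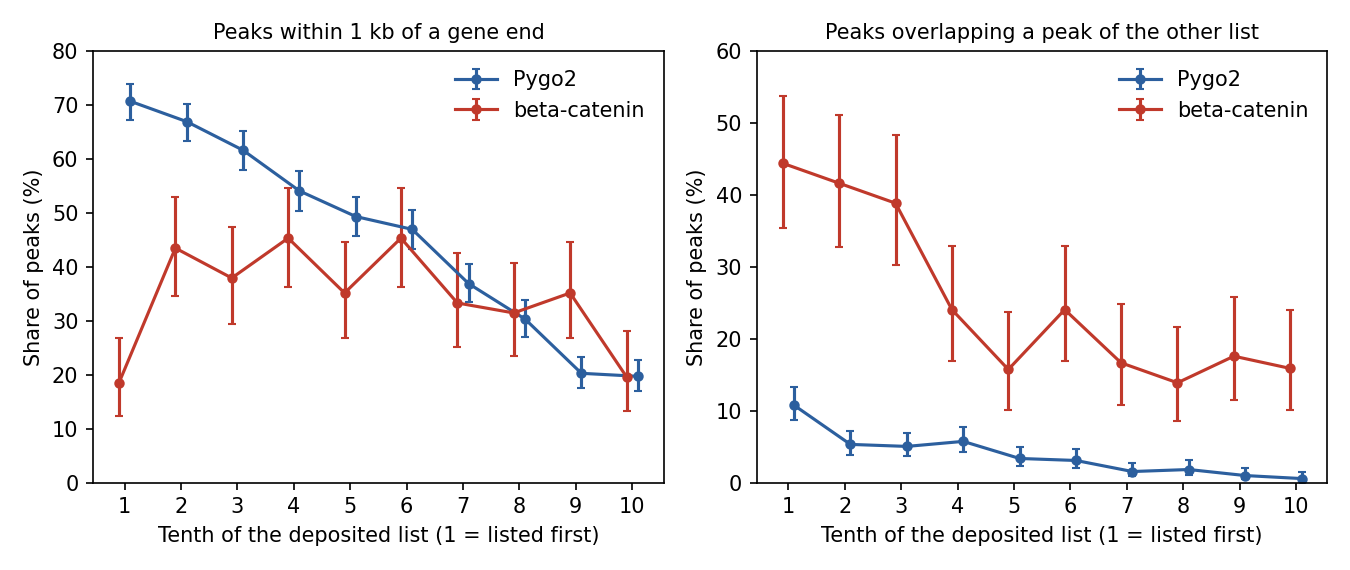
Share of peaks (%, vertical axes) within 1 kb of a gene end (left) and overlapping a peak of the other list (right), by successive 10% of the deposited list (horizontal axes, 1 to 10), for β-catenin in red and Pygo2 in blue; points are shares and bars 95% Wilson intervals. The Pygo2 gene end share declines from 70.8% to 19.7% along the list, whereas the first 10% of the β-catenin list has a low gene end share (18.5%) together with a 44.4% overlap.

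The first-listed peaks of the lists differed in their distance to gene ends. None of the 15 first-listed β-catenin peaks was within 1 kb of a gene end, 6 lay inside genes and 9 were intergenic, and 14 of the 15 were shared with Pygo2. The first 3 lay inside Acacb on chromosome 5 (114173039 to 114173207; Acacb encodes an acetyl-CoA carboxylase), inside Ybx3 on chromosome 6 (131377473 to 131377641) and in intergenic sequence 368 kb from Arid1b, a chromatin remodelling subunit gene, on chromosome 17. The next had Dtwd1, Plxdc2, Pou4f1, Bend6, Bcl11a, Aldh8a1, Cldn34c1, Gm44812, Sulf1, Gak, Lrrk1 and Gm8882 as their nearest protein-coding genes, and 9 of the 15 were more than 50 kb from any protein-coding gene end. For Pygo2, 10 of the 15 first-listed peaks were at gene ends. Of these, 3 were at genes for histone H4: the peak at H4c1 lay on chromosome 13 (23761384 to 23761550, 217 bp from the gene), that at H4c8 on chromosome 13 (23530994 to 23531160, 32 bp) and that at H4f16 on chromosome 6 (136804293 to 136804459, 56 bp). The others were at Asmt, Sirt4, Fdx2, Phf23, Jund (an AP-1 transcription factor gene), Phf12 and Kcnn1. Those away from gene ends were nearest to Acacb, Bahcc1, Dpysl2, Ybx3 and Id3. The 10 shared positions placed highest in both lists were nearest to Acacb, Ybx3, Phf23, Aurkb, Jund, Cirbp, Mus81, Ptbp1, Rras and H4c3. Positions that collect tags in every library remain a candidate explanation for the first-listed β-catenin peaks, as described below. The names therefore locate these peaks and do not establish binding there.

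Genes of the Wnt pathway were examined first, because β-catenin and Pygo2 act in it. Of 30 established Wnt target genes, 5 had a β-catenin peak within 50 kb of an end (Axin2, Lef1, Znrf3, Ccnd1 and Tnfrsf19) and 15 had a Pygo2 peak. Axin2, a negative feedback regulator of the pathway, and Lef1, a DNA-binding partner of β-catenin, carried shared peaks. At Axin2 (chromosome 11, 108917828 to 108950783) the β-catenin peak spanned 108920363 to 108920531 inside the gene, 2.62 kb from one end, and the Pygo2 peak 108920340 to 108920506. At Lef1 (chromosome 3, 131110297 to 131224357) the β-catenin peak spanned 131105935 to 131106103, 4.28 kb outside the gene, and the Pygo2 peak 131105895 to 131106061. At Ccnd1, which encodes cyclin D1, the β-catenin peak was 0.804 kb from a gene end and the nearest Pygo2 peak 1.67 kb. Lgr5, Rnf43, Nkd1, Apcdd1, Wif1, Myc and Sp8 were among the targets with a Pygo2 peak and no β-catenin peak in this window. As a list, the Wnt targets did not exceed random gene lists matched on gene spacing: the expected number was 2.34 for β-catenin (2.14-fold, permutation of gene labels, one-sided p = 0.0801, Benjamini-Hochberg adjusted p = 0.2 over 15 lists) and 11.02 for Pygo2 (1.36-fold, p = 0.0882, adjusted p = 0.189). The β-catenin call depended on the assignment of peaks: it passed with a window of 100 kb (2.42-fold, adjusted p = 0.035) and with each peak given to its nearest gene only (4.12-fold, adjusted p = 0.034), with adjusted permutation p-values from 0.034 to 0.451 over the 6 alternatives. The Pygo2 count passed without peaks at gene ends (1.92-fold, permutation, adjusted p = 0.0302, range over the alternatives 0.0302 to 1). Of 50 genes for Wnt ligands, receptors and other components, 7 had a β-catenin peak and 25 a Pygo2 peak, against 4.45 and 20.2 expected (same permutation, adjusted p = 0.281 and 0.198). The Pygo2 count of components passed under 3 alternatives (permutation, adjusted p from 0.0015 to 0.507 over the alternatives). The β-catenin count of components passed at 100 kb with 16 genes (2.26-fold, permutation, adjusted p = 0.0105, range over the alternatives 0.0105 to 1), was 0 of 50 genes at 5 kb, and was 0.522-fold with nearest genes only. The 7 genes near β-catenin peaks were Ctnnb1, the β-catenin gene itself, with Pygo1, Axin1, Dvl1, Dvl2, Wnt2 and Wnt6, and Pygo1, Dvl1 and Dvl2 had a shared peak in the window. Most of these peaks lay nearer to other genes: with nearest genes only, 1 of the 50 components kept a β-catenin peak. The shared peak 5.07 kb from Dvl2 was the position named above for Phf23, 0.247 kb from an end of that gene.

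**Figure D2:**
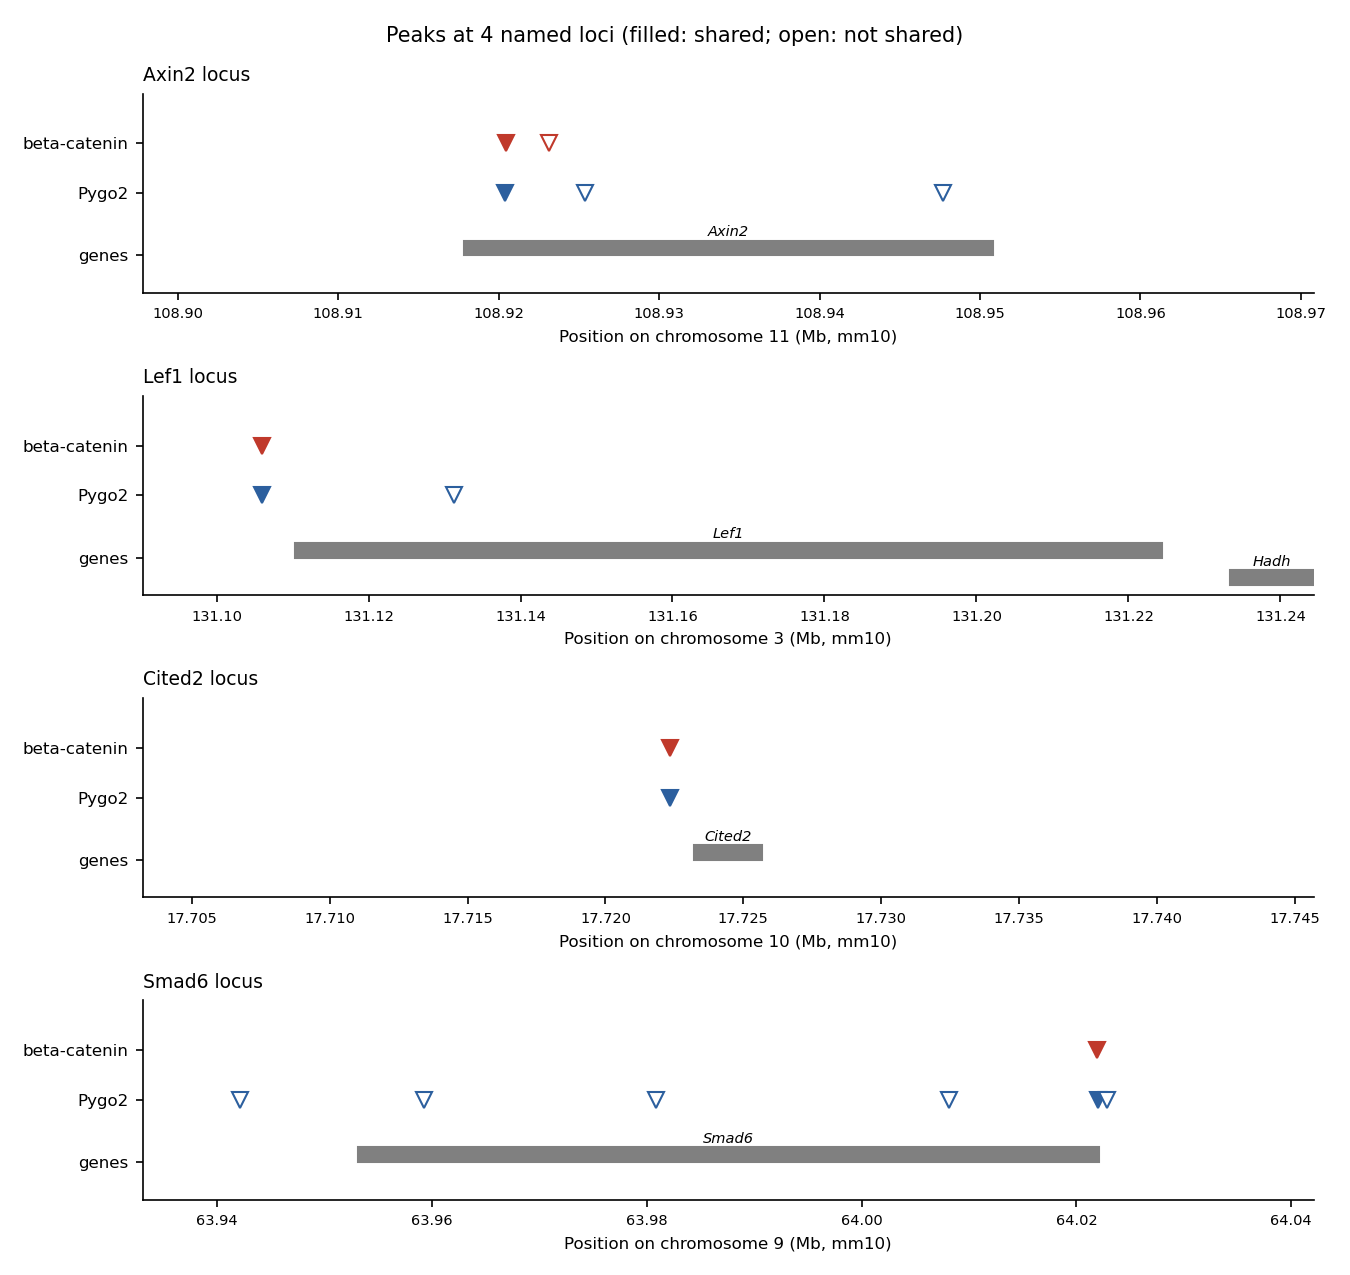
Positions of β-catenin (red) and Pygo2 (blue) peaks along the Axin2, Lef1, Cited2 and Smad6 loci (horizontal axes, Mb, mm10), each with 20 kb on either side of the gene; grey bars are protein-coding genes to scale, triangles are peak centres, filled where the peak overlaps one of the other list. Each locus has 1 filled pair, such as the β-catenin peak starting at 108920363 and the Pygo2 peak starting at 108920340 in Axin2.

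Pygo2 peaks were concentrated near genes for heart development, for arch patterning and for other signalling pathways. Of 53 heart development genes, 32 had a Pygo2 peak within 50 kb of an end, against 16.6 in matched random lists (1.93-fold, permutation of gene labels, one-sided p = 0.0001, the smallest that 10000 lists can give, adjusted p = 0.0005). They included the T-box genes Tbx1, Tbx2, Tbx3 and Tbx5, the transcription factor genes Hand2, Mef2c, Foxc1 and Foxc2, and Plxnd1, a semaphorin receptor gene. Of 42 genes of BMP, FGF, Shh and Notch signalling, 30 had a Pygo2 peak against 14.8 expected (2.03-fold, same permutation, p = 0.0001, adjusted p = 0.0005), among them Ptch1, Gli1, Gli2, Bmp4, Fgfr1, Notch1 and Dusp6, the last with a peak 0.054 kb from a gene end. Of 46 branchial arch patterning genes, 25 had a Pygo2 peak against 16.5 expected (1.52-fold, same permutation, p = 0.0041, adjusted p = 0.0154), among them Dlx1, Dlx2, Dlx5, Dlx6, Hoxa2, Barx1, Gbx2, Six2 and Alx4. These lists overlap, with 27 of the heart genes and 16 of the arch genes also on another list. The arch call ended with 1 gene kept per 200 kb (1.46-fold, permutation, adjusted p = 0.072) and with a window of 100 kb (1.32-fold, adjusted p = 0.081), in a range from 0.00225 to 0.081 over the alternatives. Ribosomal protein genes had a Pygo2 peak in 65 of 76 cases against 44.1 expected (1.47-fold, same permutation, p = 0.0001, adjusted p = 0.0005), and at 45 of the 76 it lay within 1 kb of a gene end. The random lists were matched on gene spacing and not on expression. An excess at active genes in general was therefore not separated from one particular to these lists.

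For β-catenin, 9 of the 53 heart development genes had a peak within 50 kb, among them Tbx1, Fgf8, Bmp7, Cited2, Jag1, Prrx1, Smad6 and Nrp1. All 9 also had a Pygo2 peak in the window, and at Cited2 and Smad6 the peaks of both proteins overlapped. At Smad6, an inhibitor of BMP signalling (chromosome 9, 63953076 to 64022085), the β-catenin peak at 64021885 to 64022053 lay 0.117 kb from the gene end and overlapped 1 of 7 Pygo2 peaks in the window. At Cited2, a transcriptional co-regulator gene required for heart formation (chromosome 10, 17723228 to 17725674), the β-catenin peak at 17722252 to 17722420 lay 0.893 kb outside the gene. At Jag1, a Notch ligand gene, the β-catenin peak was 0.044 kb from an end and the nearest Pygo2 peak 2.22 kb. The heart list had 3.48 genes expected (2.59-fold), with a one-sided permutation p of 0.0067 that did not pass after adjustment (adjusted p = 0.1). It passed with a window of 100 kb (1.96-fold, permutation, adjusted p = 0.048) and with nearest genes only (3.31-fold, adjusted p = 0.034), in a range from 0.034 to 0.451 over the alternatives. None of the 15 lists passed for β-catenin at 50 kb by the matched-list test, while 3 had an unadjusted p under 0.05, and 11 lay above their expectation. No arch patterning gene had a shared peak within 50 kb, although 7 of 46 had a β-catenin peak, among them Meis1 at 0.989 kb, Prrx1 and Lhx8.

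Markers of other cell types in the dissected tissue were tested in the same way. For Pygo2, 13 of 24 neural crest genes had a peak against 7.98 expected (1.63-fold, permutation of gene labels, adjusted p = 0.0765), 10 of 25 pharyngeal epithelium genes against 9.91, 7 of 20 endothelial genes against 8.63, 9 of 20 blood genes against 10.2, 7 of 22 neuronal genes against 8.04, 4 of 16 arch muscle genes against 6.51, and 17 of 24 cell cycle genes against 12.8 (adjusted p = 0.131); none of these passed at 50 kb. The neural crest count passed under 3 alternatives (permutation, adjusted p from 0.00787 to 0.109 over the alternatives). Neural crest genes with overlapping peaks of both proteins were Snai2, a repressor gene of migrating crest (0.158 kb from the β-catenin peak), and Erbb3 (1.38 kb). With each peak given to its nearest gene only, 2 of the 24 neural crest genes kept a β-catenin peak, against 3 at 50 kb. A peak within the window can thus lie nearer to another gene. Hepatocyte genes, a negative control, had a Pygo2 peak in 3 of 20 cases against 9.58 expected (0.313-fold, permutation, one-sided p for fewer = 0.0016, adjusted p = 0.012), and Hox genes in 13 of 39 cases against 23.6 (0.552-fold, p = 0.0008, adjusted p = 0.012). The 13 Hox genes belong to the HoxA and HoxC clusters, whose members can share a peak. Hox p-values from lists that were not thinned, for either protein, count such neighbours as separate genes. With 1 gene kept per 200 kb, which left 16 hepatocyte and 4 Hox genes, the folds were 0.4003 and 0.543, and neither passed with these fewer genes (permutation, adjusted p = 0.258 and 1, ranges over the alternatives 0.0315 to 1 and 0.033 to 1). Without peaks at gene ends, 10 of the 39 Hox genes had a Pygo2 peak against 11.5 expected (0.873-fold, permutation, adjusted p = 1), and at 100 kb the Hox count was 0.751-fold and the hepatocyte count 0.503-fold (adjusted p = 0.081 each). For β-catenin, 11 Hox genes, from the HoxA and HoxD clusters, had a peak within 50 kb against 6.56 expected (permutation, adjusted p = 0.181). The β-catenin Hox count passed at 100 kb (19 of 39 genes, permutation, adjusted p = 0.0105). It also passed without peaks at gene ends, where it stayed at 11 genes while the expectation fell to 2.53 (4.35-fold, permutation, adjusted p = 0.003). With 1 gene kept per 200 kb it was 1 of 4 genes (permutation, adjusted p = 0.543, range over the alternatives 0.003 to 1). It lay below its expectation at 5 kb (1 of 39 genes against 2.17, 0.46-fold) and with nearest genes only (1 against 1.38, 0.726-fold). The remaining β-catenin counts were 3 neural crest, 1 epithelial, 2 arch muscle, 4 endothelial, 1 blood, 1 neuronal, 1 hepatocyte, 19 ribosomal protein, 5 cell cycle and 7 signalling genes, with adjusted p-values from 0.181 to 0.938. Of these, neural crest and signalling genes passed at 100 kb (permutation, adjusted p = 0.0408 and 0.0367, ranges over the alternatives 0.0408 to 0.53 and 0.0367 to 0.505). Ribosomal protein genes passed with nearest genes only (2.96-fold, permutation, adjusted p = 0.034, range 0.034 to 0.777), and lay below their expectation without peaks at gene ends (4 genes against 4.84, 0.826-fold).

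**Figure D3:**
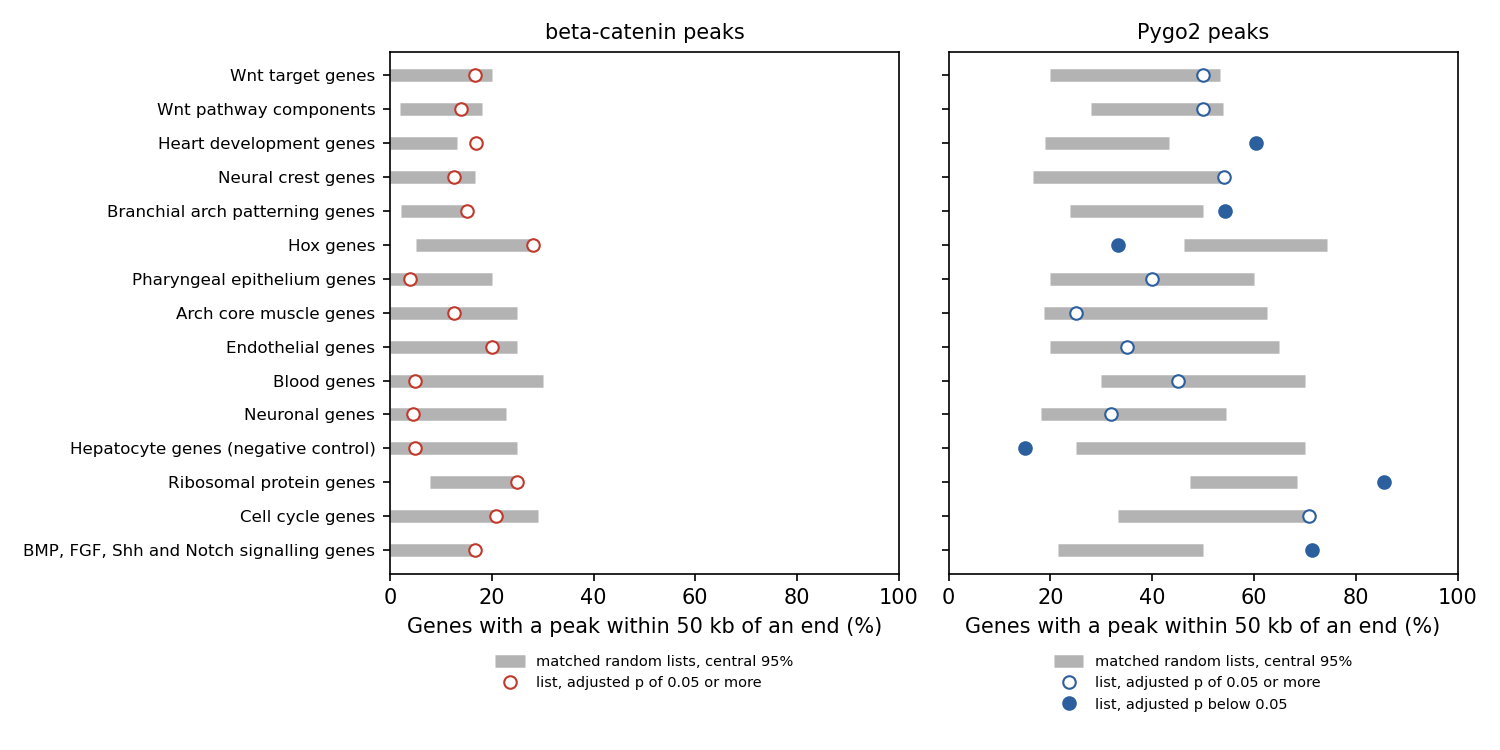
Share of the genes of each list (%, horizontal axes) with a β-catenin peak (left) or a Pygo2 peak (right) within 50 kb of a gene end; grey bars are the central 95% of 10000 random lists matched on gene spacing, and filled points are lists with an adjusted p below 0.05. The Pygo2 points for heart development (32 of 53 genes), signalling (30 of 42), arch patterning (25 of 46) and ribosomal protein genes (65 of 76) lie above their bars, those for Hox (13 of 39) and hepatocyte genes (3 of 20) below, and no β-catenin point is filled.

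The lists were compared between the proteins at equal length by drawing 1079 of the Pygo2 peaks 1000 times. The 9 heart genes near β-catenin peaks compared with a mean of 7.82 near the drawn Pygo2 peaks (central 95% of draws 4 to 12), the 5 Wnt targets with 3.81 (1 to 7), and the 7 arch patterning genes with 6.46 (2 to 11). No list differed between the proteins by this test (permutation by random draws, Benjamini-Hochberg adjusted p = 1 for each of 15 lists; the smallest unadjusted two-sided p was 0.0899, for Hox genes). With shared peaks alone no list passed either. Cell cycle genes had the smallest unadjusted value, with 4 of 24 genes (Cdc6, Mcm4, Mcm5 and Aurkb) against 1.35 expected (permutation of gene labels, one-sided p = 0.0409, adjusted p = 0.424). Of these, Aurkb was the nearest gene to its shared peak. With nearest genes only, 1 of the 24 genes kept a β-catenin peak, so the peaks near Cdc6, Mcm4 and Mcm5 lay nearer to other genes.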

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

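Alternatives based on list position, on the removal of peaks and on thinned gene lists were chosen after the data were examined. The overlap stayed above random placement under each of 11 alternatives, with folds from 14.7 for gene end peaks placed at other gene ends to 530.5 with a shortened Pygo2 list, and the lower gene end share of β-catenin kept its direction under each of 4. The number of shared β-catenin peaks, 273, was 439 with centres within 1 kb, 154 with the first-listed 50% of each list and 101 with the Pygo2 list shortened to 1079 peaks; the last 2 follow from testing fewer peaks. The number of gene lists enriched near β-catenin peaks, 0 at 50 kb, was 6 with a 100 kb window, 3 with nearest genes only and 1 (Hox genes) without peaks at gene ends; the cause was not tested. For Pygo2, the heart development, signalling and ribosomal protein lists passed under each of 6 alternatives. Counted over each of 15 lists under each of 6 alternatives, 11 Pygo2 results lost a call and 7 gained a call of enrichment. In 1 further Pygo2 result the direction reversed and a call of depletion was gained. For β-catenin, 10 results gained a call. The lost calls were those of the Hox, hepatocyte and arch patterning lists. Pharyngeal epithelium genes went from 1.01-fold to 0 of the expected number near Pygo2 peaks with a 5 kb window (permutation, adjusted p = 0.0315, up to 1 under the other alternatives), where the cause was not tested. The planned use of the stronger part of each list by score, and the motif alternatives, were not run, because the score is constant and no sequence was used. No paired analysis was possible because each list comes from 1 library. With 14.6 tags per β-catenin peak and a calling minimum of 11, positions with fewer tags were not detectable at this depth.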

Other observations

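The gene classes in this part and the tests of the 50 first-listed peaks were chosen after the values were seen. So were the test of enrichment whatever the antibody and the comparison with a shortened Pygo2 list. The tests of isolated positions and of clustered genes were written down before their results. Both proteins lay at the genes for replication-dependent histones and for transfer RNAs. For scale, 14.0% of protein-coding genes had a Pygo2 peak and 1.50% a β-catenin peak within 0.5 kb of an end. Of 63 histone genes, 52 (82.5%) had a Pygo2 peak within 500 bp, 42 of them among the 52 genes on chromosome 13 and 9 among the 10 on chromosome 3, and 15 (23.8%) had a β-catenin peak. Peaks moved by 10 to 500 kb reached a mean of 4.04 and 1.01 of these genes (12.9-fold and 14.8-fold, permutation of peak positions, one-sided p = 0.000999 each, the smallest that 1000 moves can give, adjusted p = 0.00171). Of 408 tRNA genes, 90 (22.1%) had a Pygo2 peak and 25 (6.13%) a β-catenin peak (14.8-fold and 20.2-fold, same permutation, adjusted p = 0.00171 each). Genes for small nuclear RNAs, the RNA parts of the spliceosome and related particles, had a Pygo2 peak in 28 of 1004 cases (2.79%, a lower share than for protein-coding genes) against a mean of 4.55 (same permutation, adjusted p = 0.00171) and a β-catenin peak in 6 against 0.669 (adjusted p = 0.00171). Of 1340 small nucleolar RNA genes, 8 had a Pygo2 peak against 4.88 (same permutation, adjusted p = 0.2) and 5 a β-catenin peak against 0.748 (adjusted p = 0.00959), a call that ended without shared peaks (2 genes, 3.50-fold, adjusted p = 0.169). For microRNA genes, 27 of 1228 (2.20%) had a Pygo2 peak against 8.75 (same permutation, adjusted p = 0.00171) and 2 a β-catenin peak against 1.24 (adjusted p = 0.429). None of 1110 olfactory receptor genes, which are silent in most tissues, had a peak of either protein within 500 bp, against means of 6.07 for moved Pygo2 peaks (permutation, one-sided p for fewer = 0.003) and 0.884 for moved β-catenin peaks (p = 0.398).

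The histone and tRNA pattern is not a few peaks counted repeatedly because the genes are clustered: 56 separate Pygo2 peaks lay at histone genes, against at most 13 among moved peaks, and the number of separate peaks exceeded every set of moved peaks in both lists and both classes. A candidate explanation is that immunoprecipitated chromatin is enriched at heavily transcribed short genes whatever the antibody. Both lists were enriched in both classes, with a lowest fold of 12.9, which that explanation and binding by a complex of both proteins each predict. The enrichment alone therefore cannot tell them apart, and IgG and input tags per peak were not used here. Without the peaks shared by both lists, 18 of the 25 tRNA genes kept a β-catenin peak (23.3-fold) and 84 of the 90 a Pygo2 peak, while β-catenin at histone genes fell from 15 to 5 genes (8.31-fold) and Pygo2 from 52 to 46. Near-identical copies of tRNA and histone genes also leave open how reads were divided between them.

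The 50 first-listed β-catenin peaks differed from the rest. They lay at gene ends in 1 case (2%, interval 0.354 to 10.5%), against 36.2% (interval 33.3 to 39.1%) of later peaks, a value that is part of how they were noticed. They were shared with Pygo2 in 29 cases (58.0%, against 23.7% of later peaks, Fisher's exact test, two-sided p = 7.89e-07). The centres of these shared pairs differed by a median of 5 bp, against 49.5 bp for later pairs. Of the 29, 28 lay beyond 1 kb of a gene end. This count follows from the low gene end share of the 50 peaks, so it does not test preferential recovery of open chromatin at gene ends. Positions that collect tags in every library, such as collapsed repeats, are a candidate explanation. Each listed peak had, however, passed the comparison with IgG at 2-fold or more, a filter that works against such positions. Of the 28 shared ones beyond 1 kb of a gene end, 21.4% (interval 10.2 to 39.5%) had another Pygo2 peak 1 to 20 kb away. The share was 48.6% of 105 later ones (Fisher's exact test, two-sided p = 0.0105). It was 10.6% of random positions, whose central 95% ended at 21.5%, so the value sits at the edge of the random range. The compared positions were not matched on distance to genes, where Pygo2 peaks were concentrated, so the lower share does not decide between explanations. Isolated elements bound by both proteins stay open, untested; without the 50 peaks, 244 of 1029 β-catenin peaks were shared and the fold over random placement was 223.

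The Pygo2 library held 1.10 times the tags of the β-catenin library, and its number of putative peaks before filtering was 5.42 times higher. The share of its tags in peaks was 6.40 times higher, but with 14.6 and 15.5 tags per peak this ratio follows from the number of peaks. With the Pygo2 list shortened to its 1079 first-listed peaks, the gene end shares were 70.5% (interval 67.7 to 73.2%) for Pygo2 and 34.6% (interval 31.8 to 37.5%) for β-catenin. The odds ratio was 0.221 (interval 0.184 to 0.265). The lists thus differed in more than their length, as far as list order follows peak strength. This comparison concerns where peaks lay, which can differ between antibodies at any depth. It therefore does not test depth as the source of the larger number of Pygo2 peaks. How much the unequal calling minimums of 10 and 11 tags add to the number of Pygo2 peaks was not estimated, and differences in antibody efficiency and in the number of occupied sites were not tested.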
